A study of Caenorhabditis elegans with 6 samples.

How the data were processed

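The study sequenced messenger RNA from mixed-stage hermaphrodites of the nematode Caenorhabditis elegans, a mix of embryos, larvae and adults, grown at 20 °C on plates of OP50 bacteria until crowded but not starved. It holds 6 libraries, 3 of the wild-type strain N2 and 3 of the mutant strain plp-1(ok2155). The labels call the 3 samples of each group biological replicates, and the sample titles give the group and the replicate number. Per the labels' protocols, total RNA was extracted with a phenol-based reagent and libraries were built with a stranded, poly(A)-selecting Illumina kit.

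Per the submitters' processing notes, the tools used were FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1, StringTie 1.3.4d and DESeq2. The notes give no role or order for these tools, and whether the counting used the strand is not given in the sources used here. The file labels name the WBcel235 assembly, and all coordinates are 1-based positions on it. The authors deposited 1 table of 46769 genes and 1 table of 56158 transcripts, each with a count and an FPKM value per library. The gene table holds 20090 protein-coding genes and 15364 piRNA loci. The deposited counts are estimated counts: checked against the deposited FPKM and transcript length, 100% of transcript counts between 1 and 50 lay 0 to 1 above the product of FPKM, length and a library constant, so that they had been rounded up. Every gene count equalled the sum of its transcript counts. The length of 98.8% of protein-coding gene models was a multiple of 3, so the values refer to coding length without untranslated regions. Rounding up gives a transcript with a very low estimate at least 1 count, and how reads were shared between similar copies of a gene is not shown in the tables.

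The counts were already whole and entered the tests as deposited. 24 entries without a gene symbol were left out, which held between 0.0024% and 0.0246% of the counts of a library. Every column of per-sample values was used. 20067 genes carried a WormBase identifier, of which 19720 were found in the reference name table, and exon positions came from the Ensembl gene annotation of the same assembly. CPM, the counts scaled to a common library size, used library sizes scaled by trimmed mean of M-values (TMM). Genes were kept by edgeR's filterByExpr with the group, which left 15090 genes. The main test was edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3) with the group as the single term, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Where a group held 0 counts in all libraries, the fold is a lower bound computed against a floor of 3 counts over the group, which was 0.0207 CPM in wild-type and 0.0219 CPM in plp-1(ok2155). Floors and intervals cover counting error only.

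The 25 gene lists were fixed before the data were examined, from general knowledge and patterns in gene names or descriptions. The mitochondrial gene names were matched to the symbols in the table after the symbols, and before the values, were seen. Lists with at least 5 tested members were tested with limma's camera (version 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry beside it. List levels are means of log2 CPM over the members, for which the smallest two-sided exact permutation p in an unpaired comparison of 3 with 3 is 0.1. Gene classes with at least 10 tested members were tested for enrichment with a one-sided Fisher's exact test, and chromosomes with a two-sided one, both against all tested genes. Transcripts were tested with the same edgeR model, and transcript use with edgeR's diffSpliceDGE and its Simes p per gene. The description words of the list of transposon-derived genes matched 1 gene, trt-1, which encodes the telomerase reverse transcriptase and is not transposon-derived, so the list was not tested; trt-1 had an adjusted p of 0.726.

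Genes were named by a rule fixed in advance: plp-1; up to 12 genes with the largest rise and up to 12 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups; up to 4 members with the smallest p in each list and each enriched class; and vit-2, msp-3, oma-2, col-19, end-1, his-24, glh-1, csr-1 and prg-1 whatever their p.

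Because both groups share replicate numbers, libraries of the same number were compared. Deviations of log2 CPM from the group mean correlated at 0.28, 0.21 and 0.36 for the pairs of replicates 1, 2 and 3. All lay above 0.1, while the 6 pairs with different numbers lay between -0.34 and -0.04. Deviations cancel within a group, so the negative values partly follow from the positive ones and are no separate support. With 3 libraries per group few other matchings exist, so chance alone can put the numbered matching first. The numbers were therefore taken as a possible pairing, which the main tests and the permutation p do not use. The pairing comes from this check and from the numbers in the titles; the labels do not say what a number marks. The test with the replicate as a block is given beside results whose call it changes. No 2 libraries agreed within sampling noise.

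The tests were run on simulated counts drawn from the real means and library sizes, with 200 of 15090 genes changed. Every gene had the same spread, the common value of the data, and no replicate structure was simulated. Changed genes and transcripts all had a mean of at least 20 counts. Genes with fewer counts or a larger spread can be recovered less often than the shares given here. edgeR recovered 0% of 50 genes changed by 2-fold, 32% of 50 changed by 4-fold, 90% of 50 changed by 8-fold and 100% of 50 changed by 16-fold, and 1.8% of its calls were unchanged genes. DESeq2 recovered 4% of genes changed by 2-fold, and 14.5% of its calls were unchanged genes. Of 20551 simulated transcripts, edgeR recovered 2% of those changed by 2-fold, 22% by 4-fold, 66% by 8-fold and 98% by 16-fold. For transcript use, 20 of 77 changed genes among 3217 were recovered.

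Alternatives fixed in advance were relative log expression and upper-quartile normalization, no filter on low counts, the replicate block, leaving out each library in turn, DESeq2 (version 1.42.0), and limma on log2(FPKM + 1) and log2(FPKM + 0.1). Others were a minimum of 2-fold, an adjusted p under 0.01, TMM factors computed without sperm, collagen and yolk genes, and, for transcripts, a minimum of 10 counts in all as the single filter. Added after the data were seen were counts rebuilt without the rounding up, 1 surrogate variable from sva (version 3.50.0), and results without the run of genes on chromosome II described in the results.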

Results

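The data compare gene and transcript counts of mixed-stage hermaphrodites of the nematode Caenorhabditis elegans between the wild-type strain N2 (3 libraries) and the mutant plp-1(ok2155) (3 libraries). The series title gives the purpose as transcriptome profiling of plp-1 mutants; plp-1 encodes a relative of the Pur-alpha family of nucleic acid binding proteins. Total counts were 53486099, 50106030 and 39331848 in wild-type replicates 1, 2 and 3, and 46665815, 46800016 and 41925388 in plp-1(ok2155) replicates 1, 2 and 3. Protein-coding genes took between 97.28% and 98.52% of the counts. The 6 yolk protein (vitellogenin) genes took 4.48%, 8.31% and 13.54% of the counts in the wild-type libraries and 6.19%, 4.81% and 9.38% in the mutant libraries, so that libraries of one group differed in this marker of adults. On the first principal component of log2 CPM (38.8% of the variance) the wild-type libraries lay between -69.6 and -33.8 and the mutant libraries at 79, 74.2 and 2.4. Wild-type replicate 1 stood apart on the second (27.8%), at 95.8 against -51.7 to 23.9 for the others. The biological coefficient of variation was 47.1%.

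The comparison asked which transcripts differed between plp-1(ok2155) and wild-type animals. In the mutant the transcript of plp-1 itself fell, and 5 of 20 tested genes known as targets of endogenous small RNA silencing rose. A run of 24 consecutive genes with any count on chromosome II held 1 mutant count against 6122 in wild-type. Of these genes 14 belong to the F-box and MATH/BTB families and 10 do not. Of single genes, haf-6, an ABC transporter needed for efficient RNA interference, and tiar-2, an RNA-binding protein of the TIA-1 family, fell. Transcripts of sperm and of cuticle collagens had mostly positive log2 fold changes as groups, and those of the mitochondrial genome negative ones.

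The gene plp-1 (gene ID 177540) has its coding span on chromosome IV from 7633430 to 7634431 in the gene table, and the annotation places it on the plus strand with 4 exons, from the 5' untranslated region at 7633360 to the end of the 3' untranslated region at 7634653. It held 18944, 20356 and 12639 counts in the wild-type libraries and 920, 888 and 959 in the mutant libraries. Its level was 367.5 ± 69.2 CPM (SD, n = 3) in wild-type and 20.4 ± 2.7 CPM (SD, n = 3) in plp-1(ok2155). The log2 fold change was -4.17 (SE 0.28, edgeR's quasi-likelihood test, adjusted p = 0.00242). It was lower than every wild-type library in 3 of 3 mutant libraries. The tables give counts per gene and transcript, so the part of the gene from which the remaining counts came was not analysed here.

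**Figure D1:**
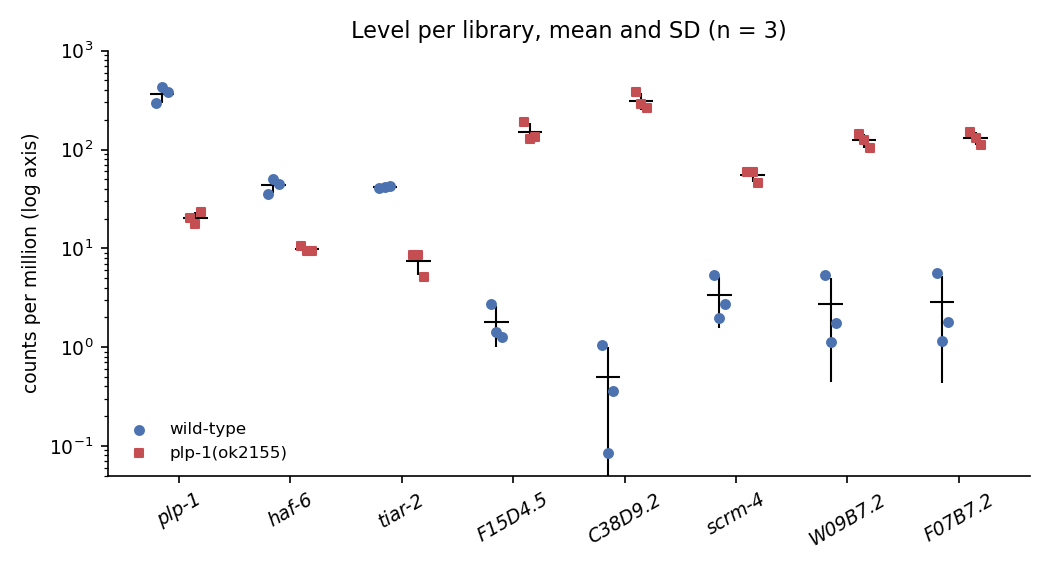
CPM (log axis) of 8 genes in each library, with wild-type libraries as circles and plp-1(ok2155) libraries as squares; horizontal lines are group means and vertical lines 1 SD (n = 3). The genes plp-1, haf-6 and tiar-2 lay lower in all 3 mutant libraries and the 5 small RNA target genes higher; the SD of C38D9.2 in wild-type (0.499) is as large as its mean and runs off the axis.

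Of 15090 genes tested, 40 were higher and 12 were lower in plp-1(ok2155). All 52 changed by at least 2-fold and showed no overlap between the groups. Among all tested genes 14.2% showed no overlap, where chance gives 10%. The largest rises were in genes almost silent in wild-type. C38D9.2 (gene ID 183313, chromosome V from 17569380 to 17571603) rose from 0.499 ± 0.499 to 310.3 ± 60.8 CPM (SD, n = 3), a log2 fold change of 9.21 (SE 0.84, edgeR adjusted p = 0.00847), which was 10.52 without wild-type replicate 1. F15D4.5 (gene ID 174969, chromosome II from 13245430 to 13247644) rose from 1.8 ± 0.805 to 150.8 ± 33.3 CPM, a log2 fold change of 6.37 (SE 0.42, edgeR adjusted p = 0.00242). T28F2.1 (gene ID 189047, chromosome I from 3639648 to 3641347) had 0 counts in all wild-type libraries and 5.2 ± 0.907 CPM in the mutant, at least 252-fold higher. C55C3.7 held 2 counts over the wild-type libraries and 761 over the mutant libraries, a ratio of 403 with a 95% counting interval from 111 to 3337; without wild-type replicate 1, which held both counts, it was at least 145-fold higher. C55C3.6 beside it on chromosome IV rose by 6.03 (SE 0.71) on the log2 scale.

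Further rises were log2 fold changes of 6.87 for C38D9.13, a noncoding gene next to C38D9.2, 5.69 for C43E11.5 on chromosome I and 5.54 for C27D8.2 on chromosome IV. C27D8.2 shares 195 exonic bases with its neighbour C27D8.3 on the opposite strand. The pair W09B7.1 and W09B7.2 and the pair F07B7.1 and F07B7.2 on chromosome V had almost equal counts; their sequence identity was not measured here, so whether reads were shared between the pairs is open. Log2 fold changes were 9.07 for W09B7.1, 9.11 for F07B7.1, 5.48 for W09B7.2 and 5.51 for F07B7.2, and wild-type replicate 1 held all 26 wild-type counts of W09B7.1 and all 26 of F07B7.1. Without that library W09B7.1 and F07B7.1 were at 0 in wild-type and at least 2283-fold and 2352-fold higher, and the log2 fold changes were 6.44 for W09B7.2, 6.48 for F07B7.2, 7.86 for C38D9.13 and 6.24 for C27D8.2. Without wild-type replicate 2 they were 8.42 for W09B7.1, 8.47 for F07B7.1 and 6.22 for C38D9.13. The edgeR adjusted p of these 7 genes lay between 0.00669 and 0.0345.

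Beside plp-1, 4 genes fell from a mean of at least 5 CPM in wild-type. The gene haf-6 (gene ID 171694, chromosome I from 1162953 to 1175753), which shares 44 exonic bases with a gene on the opposite strand, fell from 43.6 ± 7.52 to 9.79 ± 0.725 CPM (SD, n = 3), a log2 fold change of -2.15 (SE 0.28, edgeR adjusted p = 0.0267). The gene tiar-2 (gene ID 174909, chromosome II from 12768742 to 12773222) fell from 41.6 ± 1.38 to 7.43 ± 2 CPM, a log2 fold change of -2.48 (SE 0.32, edgeR adjusted p = 0.0267). The F-box genes fbxc-42 and fbxc-40, on either side of fbxc-39 on chromosome II, had 0 counts in all mutant libraries and were at least 378-fold and 265-fold lower. In all, 8 of the 12 lower genes had 0 counts in every mutant library.

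At an unadjusted p under 0.05, 960 genes were higher and 483 lower, where chance alone gives a share of 0.05 of the 15090 tested genes over both directions together. The same share, again over both directions together, applies to the unadjusted counts given below for lists and transcripts. With the replicate as a block, 155 genes were higher and 64 lower, including all 40 and all 12 above. Without wild-type replicate 1 the counts were 18 higher and 5 lower; without wild-type replicate 2 they were 0 and 1 (edgeR; 899 and 977 at an unadjusted p under 0.05), without wild-type replicate 3 they were 1 and 1, and without mutant replicates 1, 2 or 3 they were 5, 3 or 4 higher and 1 lower each time. DESeq2 called 463 higher and 100 lower.

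Genes known from the field as silenced by endogenous small RNAs stood out. Of the 20 tested members of that list, 5 rose and none fell over all genes; adjusted over the list alone, 8 rose. The 5 were C38D9.2, F15D4.5, W09B7.2, F07B7.2 and scrm-4 on chromosome I, a member of the phospholipid scramblase family. The gene scrm-4 rose from 3.38 ± 1.8 to 54.6 ± 7.19 CPM (SD, n = 3), a log2 fold change of 4.01 (SE 0.44, edgeR adjusted p = 0.0198), and shares 77 exonic bases with kpc-1 on the opposite strand. The list's median log2 fold change was 1.13, 16 of 20 members were positive, and camera gave an adjusted p of 1.4e-08. The call was lost with an estimated correlation (adjusted p = 0.289 with an estimated correlation), and fry gave an adjusted p of 0.00442. With the replicate block 6 members rose.

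The machinery of those pathways, 81 Argonautes, RNA-dependent RNA polymerases and germ granule factors, had no member past the threshold over all genes or adjusted over the list alone (4 higher and 0 lower at an unadjusted p under 0.05, 2 higher with DESeq2). Its median log2 fold change was 0.24 and camera gave an adjusted p of 0.0302 in the higher direction (adjusted p = 0.936 with an estimated correlation). That call was lost without wild-type replicate 3 (adjusted p = 0.478), without mutant replicate 1 (0.574) and without mutant replicate 2 (0.123). The sperm Argonautes alg-4 and alg-3 had log2 fold changes of 3.29 (edgeR adjusted p = 0.136) and 3.35 (0.283). The piRNA-binding Argonaute prg-1 had a log2 fold change of 0.70 (0.406), the Argonaute csr-1 0.34 (0.725) and the germ granule helicase glh-1 0.38 (0.692).

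Sperm transcripts were higher in the mutant libraries as groups, without a single member past the threshold over all genes in edgeR. All 31 tested members of the major sperm protein family, the cytoskeletal proteins of nematode sperm, had positive log2 fold changes with a median of 3.14, and adjusted over the list alone all 31 rose, as many as had an unadjusted p under 0.05; DESeq2 called 30. The camera adjusted p was 3.1e-31 (adjusted p = 0.354 with an estimated correlation), and fry an adjusted p of 0.0725. The list's mean level was -0.83 ± 0.86 log2 CPM (SD, n = 3) in wild-type and 2.19 ± 0.99 in plp-1(ok2155), with 2.64, 2.87 and 1.05 in the 3 mutant libraries. The exact permutation p of that difference was 0.1, the smallest possible. Members msp-55, msp-49 and msp-3 had log2 fold changes of 3.33, 2.75 and 3.69, with edgeR adjusted p of 0.0998, 0.101 and 0.105; with the block that of msp-55 was 0.0443, and 2 members of the family were called. Reads of the near-identical msp genes could be split between copies. Of 53 other spermatogenesis genes, none was called over all genes, 31 rose adjusted over the list alone, and 3 rose with the block; 35 had an unadjusted p under 0.05 and DESeq2 called 27. Their median was 2.60, and camera gave an adjusted p of 1.8e-24 (adjusted p = 0.354 with an estimated correlation). The sperm genes smz-1 and nspd-6 had log2 fold changes of 2.90 and 3.58 (edgeR adjusted p = 0.0694 and 0.0854; with the block 0.0261 and 0.0422).

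No oocyte or meiosis gene was called over all genes in edgeR. The 36 oocyte and maternal genes had a median log2 fold change of 0.51 and 31 positive members, none called over all genes or adjusted over the list alone (4 higher at an unadjusted p under 0.05, 0 with DESeq2). The camera adjusted p was 0.00152 (adjusted p = 0.936 with an estimated correlation), which was 0.064 without wild-type replicate 3 and 0.268 without mutant replicate 1. The maternal RNA-binding protein genes mex-5 and mex-3 had log2 fold changes of 1.12 and 0.91 (edgeR adjusted p = 0.434 and 0.485), and oma-2 0.38 (0.804). The 35 meiosis genes had a median of 0.01, which turned to -0.02 with upper-quartile normalization, and no member was called over all genes or adjusted over the list alone (1 higher at an unadjusted p under 0.05, 1 with DESeq2). By camera the adjusted p was 0.679. The member with the smallest p was rad-50, a DNA repair gene, at 0.97 (edgeR adjusted p = 0.203).

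**Figure D2:**
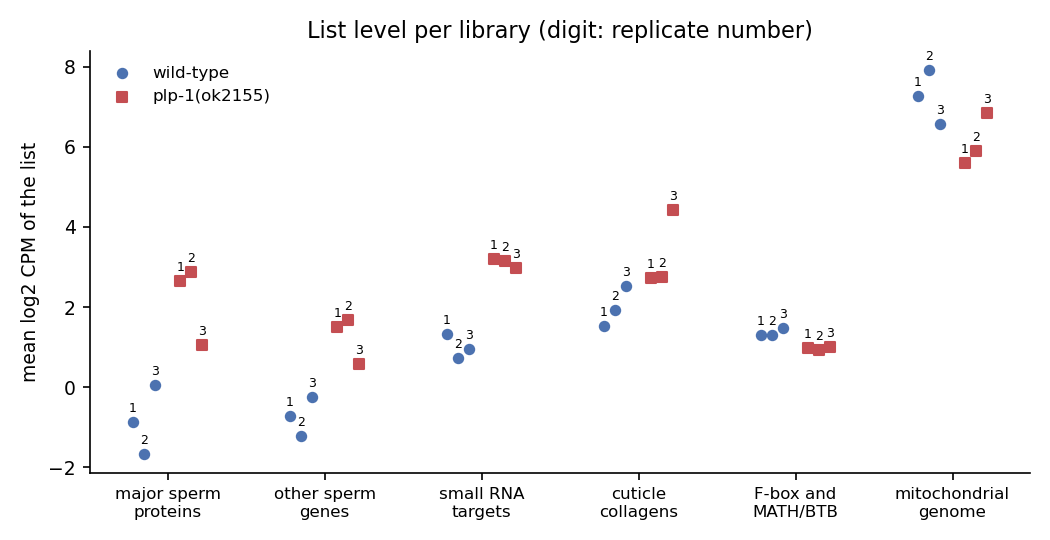
Mean log2 CPM of 6 gene lists in each library, wild-type as circles and plp-1(ok2155) as squares, with the replicate number above each point. Major sperm proteins lay at 2.64, 2.87 and 1.05 in the mutant libraries, small RNA targets at 3.19, 3.14 and 2.98, and collagens were highest in mutant replicate 3 (4.41).

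Collagens of the cuticle, the outer coat that is rebuilt at each larval moult, had a median log2 fold change of 1.28 over 144 tested genes, of which 112 were positive. Over all genes 1 rose, sqt-1, from 0.398 ± 0.104 to 5.89 ± 2.81 CPM (SD, n = 3), a log2 fold change of 3.89 (SE 0.56, edgeR adjusted p = 0.0382). Adjusted over the list alone 32 rose, and with the replicate block 32 rose over all genes. With the block, the col class was enriched among the higher genes, with 22 of 120 members against 1.23 expected (one-sided Fisher's exact test, adjusted p = 2.6e-19); without it no class was enriched among the higher genes. Camera gave an adjusted p of 8.8e-13 (adjusted p = 0.611 with an estimated correlation). The genes col-138, rol-6 and sqt-2 had log2 fold changes of 4.69, 3.32 and 3.44 (edgeR adjusted p = 0.073, 0.0937 and 0.096; with the block 0.000972, 0.031 and 0.0404). The adult collagen col-19 had a log2 fold change of -0.26 (0.893), which turned to 0.07 without wild-type replicate 3. The 60 moulting genes had no member called over all genes, with 1 higher adjusted over the list alone, wrt-7, a hedgehog-related gene, at 2.73 (edgeR adjusted p = 0.073; with the block 0.0323). At an unadjusted p under 0.05, 3 were higher and 1 lower, and DESeq2 called 1 and 1. Their median was 0.06 and their mean -0.04; the camera adjusted p was 0.193 in the higher direction, and 5.8e-05 without wild-type replicate 1.

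Among markers of tissues and stages, 24 muscle genes had a median log2 fold change of 0.27, with none called over all genes (3 higher at an unadjusted p under 0.05, 2 with DESeq2) and 2 higher adjusted over the list alone. These were unc-89 and unc-22, giant proteins of the sarcomere, at 1.25 and 1.88 (edgeR adjusted p = 0.127 and 0.136; with the block 0.0323 and 0.012). Without wild-type replicate 1 unc-22 was called, at 2.52 (adjusted p = 0.0409). In the test of single transcripts with all 6 libraries, 2 transcripts of unc-22 were called higher (edgeR adjusted p = 0.00962 and 0.0183). With the block no transcript was called. Camera gave an adjusted p of 0.0116 for the muscle list (adjusted p = 0.354 with an estimated correlation), which was 0.101 without wild-type replicate 2 and 0.157 without mutant replicate 3. The 61 neuronal genes had a median of -0.32 and none called by edgeR, over all genes, adjusted over the list alone or at an unadjusted p under 0.05, nor by DESeq2. Camera gave an adjusted p of 0.00139 in the lower direction (adjusted p = 0.769 with an estimated correlation), and 0.101 without wild-type replicate 1. The neuropeptide gene flp-27 and the proprotein convertase gene egl-3 were at -0.96 and -0.78 (edgeR adjusted p = 0.526 and 0.555).

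The 6 vitellogenins had a median of -0.58 and vit-4 and vit-2 stood at -0.87 and -0.41 (edgeR adjusted p = 0.78 and 0.84); vit-2 turned to 0.18 without wild-type replicate 3. Their camera adjusted p was 0.557, and 0.00159 without wild-type replicate 1. The 16 intestinal genes had a median of -0.53 and a camera adjusted p of 0.0653, which was 0.0305 with the block (adjusted p = 0.503 with the block and an estimated correlation), 0.0043 without wild-type replicate 1, 0.023 without wild-type replicate 2 and 0.0112 without mutant replicate 3; cpr-3, a cathepsin B-like protease, stood at -1.59 (edgeR adjusted p = 0.249). The 49 endoderm and early zygotic genes, markers of embryos, had a median of 0.33 and a camera adjusted p of 0.109, which was 0.000924 without wild-type replicate 2 and 0.000532 without mutant replicate 3. In this list sdz-35 stood at -3.21 (edgeR adjusted p = 0.109), and the endoderm factors end-3 and end-1 at 1.69 (0.186) and 0.58 (0.855), the last turning to -0.117 without mutant replicate 1. No vitellogenin, intestinal or embryonic gene was called over all genes or adjusted over the list alone; at an unadjusted p under 0.05 there were 0, 2 (lower) and 5 (3 higher, 2 lower), and with DESeq2 0, 1 (lower) and 3 (2 higher, 1 lower).

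The F-box and MATH/BTB families, large families of substrate adaptors of ubiquitin ligases, held 6 of the 12 lower genes. Of 370 tested members, 6 fell and 1 rose over all genes, and 10 fell and 1 rose adjusted over the list alone. With the block 11 fell and 1 rose over all genes. At an unadjusted p under 0.05, 31 were lower and 5 higher, and DESeq2 called 17 lower and 2 higher. The median log2 fold change was -0.20; camera gave an adjusted p of 0.000315 in the lower direction (adjusted p = 0.354 with an estimated correlation), fry gave an adjusted p of 0.0645, and its test of change in either direction gave 8.6e-05. Among gene classes, fbxb (3 of 98 members, adjusted p = 0.0138) and fbxc (2 of 38, adjusted p = 0.0493) were enriched among the lower genes by one-sided Fisher's exact test. With the replicate block fbxc was enriched (4 of 38, adjusted p = 0.0024) and fbxb was not (4 of 98, adjusted p = 0.0647).

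The lower F-box genes lay in a single run of genes, with other genes between them. On chromosome II, 24 consecutive genes with any count, from C32B5.6 at 968406 to the end of fbxb-40 at 1049821 (81.4 kb), held 6122 counts over the wild-type libraries and 1 count over the mutant libraries. At the wild-type share, 5799 counts would be expected in the mutant libraries. All 7 lower genes of the run, fbxc-40, fbxc-42, C32B5.15, btb-11, fbxb-41, fbxb-45 and fbxb-40, had 0 mutant counts and were at least 40.9-fold to 378-fold lower. The gene fbxc-14 in the run, at 0 in the mutant, was at least 43.1-fold lower and did not pass the threshold (edgeR adjusted p = 0.0721; with the block 0.0303). With the block 14 genes of the run were lower, the 7 above and fbxc-14, fbxc-39, fbxb-30, math-34, F45D11.14, F45D11.15 and F45D11.16. Next to the run, fbxc-18 on the left held 632 wild-type and 711 mutant counts. On the right M01D1.11, a snoRNA gene, held 2 and 0, K02E7.7 held 88, 27 and 17 in the wild-type libraries and 9, 6 and 9 in the mutant libraries, K02E7.6 held 331 and 385 over the groups, btb-10 held 661 and 883 and K02E7.5 held 200 and 52. The 16 genes nearest the run on both sides held 2960 and 2922. Without the run, 5 genes were lower and neither class was enriched, while 3 gene lists were lower by camera, as many as with the run. This was computed after the run had been seen. C32B5.15, btb-11, math-34, the F45D11 genes and the flanking genes were named after their values were seen.

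**Figure D3:**
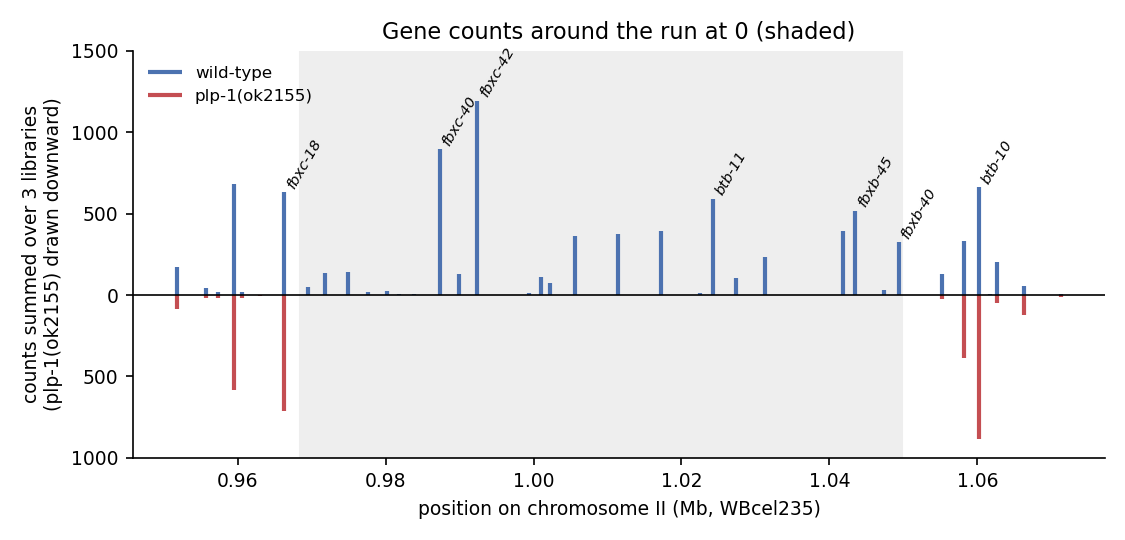
Counts per gene summed over 3 libraries against position on chromosome II, with wild-type drawn upward and plp-1(ok2155) downward. The shaded run of 81.4 kb holds 6122 wild-type counts and 1 mutant count, while genes on both sides hold counts in both groups.

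Of the 12 protein genes of the mitochondrial genome, all had negative log2 fold changes, with a median of -0.73. None was called over all genes by edgeR and 3 fell adjusted over the list alone; 5 were lower at an unadjusted p under 0.05, and DESeq2 called 3. The list's mean level was 7.27, 7.92 and 6.58 log2 CPM in the wild-type libraries and 5.6, 5.89 and 6.84 in the mutant libraries, so that the groups overlapped (exact permutation p = 0.2). Camera gave an adjusted p of 1.7e-06 (adjusted p = 0.354 with an estimated correlation). ATP6 and ND2, subunits of ATP synthase and complex I, had log2 fold changes of -1.19 and -1.50 (edgeR adjusted p = 0.136 and 0.19). The libraries were selected for poly(A), so the values describe the captured part of these transcripts. The 34 nuclear genes of the respiratory chain had a median of 0.07 and a camera adjusted p of 0.36, which was 0.0452 without wild-type replicate 3, and none was called over all genes or adjusted over the list alone (1 higher at an unadjusted p under 0.05, 1 with DESeq2); cyc-2.2, a cytochrome c gene, stood at 3.34 (edgeR adjusted p = 0.154).

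The remaining lists did not pass the camera test. The adjusted p was 0.557 for 31 heat shock and stress genes, 0.607 for 174 detoxification genes, 0.526 for 191 innate immunity genes, 0.21 for 25 intracellular pathogen response genes, 0.0653 for 76 chemoreceptor genes, 0.0653 for 60 histone genes, 0.404 for 80 ribosomal protein genes and 0.842 for 67 lipid metabolism genes. Medians lay between -0.42 for chemoreceptors and 0.27 for histones; that of immunity genes, 0.01, turned to -0.01 with upper-quartile normalization. Median and camera direction were negative but the mean positive for pathogen response genes (-0.12 and 0.29) and lipid metabolism genes (-0.09 and 0.01). With the replicate block, chemoreceptors (adjusted p = 0.0294) and intracellular pathogen response genes (0.0489) passed in the lower direction and histones (0.0298) in the higher one. With the block and an estimated correlation the adjusted p was 0.494, 0.818 and 0.834 in the same order. Without wild-type replicate 1, ribosomal protein genes (2.3e-05), detoxification genes (0.031) and chemoreceptors (0.00909) passed in the lower direction, and without mutant replicate 3 the pathogen response genes did (0.000532). Chemoreceptors also passed without mutant replicate 2 (0.00474) or 3 (0.00694), and histones without wild-type replicate 2 (0.0101) or mutant replicate 3 (0.000216). Without mutant replicate 1 the immunity genes passed in the higher direction (0.0207). No member of these 8 lists was called over all genes by edgeR. At an unadjusted p under 0.05, stress genes had 0 higher and 3 lower, detoxification genes 9 and 10, immunity genes 14 and 9, pathogen response genes 2 and 2, chemoreceptors 3 and 4, histones 1 and 2, ribosomal protein genes 0 and 0 and lipid metabolism genes 4 and 6. DESeq2 called 0 and 1, 3 and 2, 4 and 2, 0 and 0, 1 and 0, 0 and 0, 0 and 0, and 2 and 1 in the same order of lists. With the block, detoxification genes had 1 higher and 3 lower, immunity genes 1 and 1, pathogen response genes 0 and 2 and lipid metabolism genes 1 and 2. The gene acdh-8, an acyl-CoA dehydrogenase, was the single one adjusted over the list alone, at 3.66 (edgeR adjusted p = 0.073; with the block 0.0115). The smallest p of the other lists belonged to hsp-12.6 at -2.38 (edgeR adjusted p = 0.268), ugt-41 at 1.86 (0.104; with the block 0.0103), pals-27 at 2.23 (0.32), his-52 at -1.80 (0.516) and rps-13 at -0.40 (0.713). The genes clec-73, a C-type lectin, and srw-120, a chemoreceptor, had 0 counts in all wild-type libraries, were at least 61.4-fold and 15.6-fold higher, and had edgeR adjusted p of 0.086 (with the block 0.0193) and 0.105. The linker histone his-24 stood at 0.06 (0.983) and was negative with upper-quartile normalization (-0.032).

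The changed genes were spread unevenly over the chromosomes. Chromosome IV, which holds plp-1, carried 18 of the 40 higher genes against 6.75 expected from its 2547 tested genes, an odds ratio of 4.05 (95% interval 2.04 to 7.92, two-sided Fisher's exact test, adjusted p = 0.000363). Chromosome II carried 8 of the 12 lower genes against 2.11 expected, an odds ratio of 9.42 (95% interval 2.52 to 42.8, adjusted p = 0.00135), and 7 of the 8 lay in the run above. Without the run the odds ratio of chromosome II was 1.18 (adjusted p = 1). The X chromosome carried 1 higher gene against 5.76 expected (odds ratio 0.152, adjusted p = 0.0957). With the replicate block the odds ratios were 2.44 for chromosome IV (51 of 155 higher genes) and 2.31 for chromosome II (21 of 64 lower genes). Of the 21, 14 lay in the run, and an odds ratio without the run was not computed with the block. With it the X chromosome carried 5 of 155 against 22.3 expected (odds ratio 0.196, adjusted p = 4.9e-05), and chromosome I carried 3 of 64 lower genes against 10.2 expected (odds ratio 0.257, adjusted p = 0.0287).

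**Figure D4:**
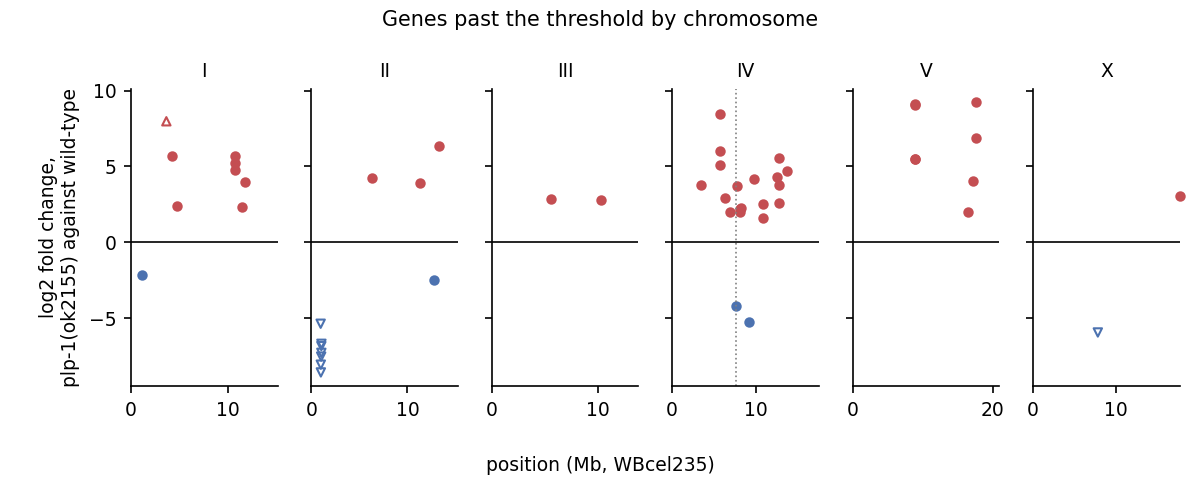
Log2 fold change of the 52 genes past the threshold against position on each chromosome, higher genes in red and lower genes in blue; the dotted line marks plp-1 and open triangles are lower bounds for genes with 0 counts in a whole group. Chromosome IV holds 18 of the 40 higher genes, and 7 lower genes sit in the chromosome II run.

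At the level of transcripts, 9 of 20551 were higher and 3 were lower; with the replicate block edgeR called 0 and 0 (1467 and 1113 at an unadjusted p under 0.05; DESeq2 was not run on transcripts). The 12 belonged to 11 genes, of which 7 were called in the gene test. Transcript use, the share of a gene's counts taken by each of its transcripts, changed in 12 of 3288 genes, none of them called in the gene test, and in 4 with the block. In agt-1, a DNA alkyltransferase gene with 2 tested transcripts, 1 took 56.8 ± 3.3% of the counts in wild-type and 0.3 ± 0.1% in plp-1(ok2155) (SD, n = 3, diffSpliceDGE in edgeR, adjusted p = 9.2e-06). In F44E7.4, 1 of 4 transcripts went from 29 ± 5.2% to 0.1 ± 0.1% (adjusted p = 7.3e-12). In acl-5, an acyltransferase gene, 1 of 2 transcripts went from 0.4 ± 0.1% to 43.8 ± 13.4% (adjusted p = 9.5e-05). In lin-17, a Frizzled receptor gene of the Wnt pathway, 1 of 2 transcripts went from 0% to 56.6 ± 16.5% (adjusted p = 0.00617; with the block 0.0935, and without mutant replicate 3 it was 0.0582). These shares rest on the authors' estimated assignment of reads to transcripts. Without 1 library the count of higher transcripts lay between 0 (without mutant replicate 2) and 21 (without wild-type replicate 1); it was 1 without wild-type replicate 2 or mutant replicate 1, 3 without wild-type replicate 3 and 5 without mutant replicate 3. Lower transcripts numbered 0 without mutant replicates 1 or 2. Transcript use was called in 7 genes without mutant replicate 1 or 3.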

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

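The surrogate variable, the counts without rounding up and the tests without the chromosome II run were chosen after the data were seen; the other alternatives were fixed before the data were examined. The fall of plp-1 held its direction and its side of the threshold with the other normalizations, no filter, the block, DESeq2, both limma settings and without each library in turn, with log2 fold changes from -4.34 to -4.08. In simulated data with the same spread for every gene, 32% of genes changed by 4-fold were recovered, and depth limited genes at 0 to the bounds given.

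Genes higher and lower numbered 155 and 64 with the replicate block, 463 and 100 with DESeq2, and 65 and 21 with limma on log2(FPKM + 0.1). They numbered 5 and 1 at an adjusted p under 0.01, where the stricter threshold is the cause, and 83 and 19 with 1 surrogate variable; of the others the cause was not tested. DESeq2 gave no adjusted p for 120 genes. All 40 higher and all 12 lower genes were also called with the block, with DESeq2 and with the surrogate variable; limma with 0.1 called 38 and 12 of them, and limma on log2(FPKM + 1) 22 and 7. Leaving out 1 library gave 0 to 18 higher and 1 to 5 lower genes. With 5 libraries the test has fewer samples, which is one cause of that loss. Without the chromosome II run 5 genes were lower, by construction. The counts stayed within 1.5 times with relative log expression (40 and 11), upper-quartile normalization (28 and 8), no filter on low counts (36 and 10), limma on log2(FPKM + 1) (27 and 8), counts without rounding up (41 and 11), a minimum of 2-fold, and TMM factors without sperm, collagen and yolk genes.

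Gene lists higher and lower, 7 and 3, became 0 and 0 when an estimated correlation replaced camera's preset correlation of 0.01. The switch from a preset to an estimated correlation was the single setting changed there. Which part of what that switch alters in the test caused the loss was not tested. Fry gave 1 higher and 0 lower lists, and the cause of that change was not tested. With the replicate block 6 lists were lower. Leaving out 1 library gave 6 to 8 higher and 3 to 7 lower lists, with 7 lower without wild-type replicate 1 and 6 without mutant replicate 3. Beside the lists named with the results, histone genes passed with upper-quartile normalization (adjusted p = 0.0457), embryonic genes passed with no filter (0.0309), and germ granule genes did not pass with no filter (0.0515).

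Gene classes enriched among higher genes numbered 1 with the block and 3 with DESeq2, against 0, and among lower genes 1 with the block and 0 without the run, against 2. Chromosome shares past the threshold numbered 4 with the block, 6 with DESeq2 and 1 without the run, against 2. The losses without the run follow from leaving out its lower genes, and the cause of the other changes was not tested.

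Transcripts higher and lower, 9 and 3, became 0 and 0 with the block, and 0 to 21 and 0 to 3 without 1 library. Genes with changed transcript use, 12, became 4 with the block, 7 with a minimum of 10 counts as the single filter, and 7 to 15 without 1 library; the cause was not tested.

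Of 38 genes past the threshold other than plp-1, which are those named here with swt-3 and F13H8.8, none changed direction under the alternatives listed for plp-1. Leaving out 1 library ended 197 of their calls, between 20 (without wild-type replicate 1) and 38 (without wild-type replicate 2) at a time; limma on log2(FPKM + 1) ended 13, upper-quartile normalization 11 and no filter 4. Of 42 named genes not past it, 13 passed with the block and 26 with DESeq2. Signs turned for his-24 with upper-quartile normalization (-0.032), no filter (-0.02), the block (-0.1), limma (-0.066 and -0.068), and without wild-type replicate 2 (-0.115), wild-type replicate 3 (-0.216) or mutant replicate 1 (-0.554). They also turned for vit-2 (0.181) and col-19 (0.07) without wild-type replicate 3 and for end-1 (-0.117) without mutant replicate 1. Without 1 library the range was -0.554 to 0.341 for his-24, -0.75 to 0.181 for vit-2, -0.648 to 0.07 for col-19 and -0.117 to 1.51 for end-1. Another scaling moved the median of all genes, -0.032, to at most -0.0487.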

Other observations

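The genes named in this and the next paragraph, the count of neighbouring genes in random sets, and the tests of depth and of the mix of stages were chosen after the result was seen. Higher genes often lay next to each other, and 18 of the 40 fell into 7 groups with gaps under 20 kb. Among 10000 random sets of 40 tested genes the median was 0 such genes and the largest number 10. The random sets take genes as independent and ignore copies and shared exonic bases. The groups include the W09B7 and F07B7 pairs, and C27D8.2 with C27D8.3. On chromosome IV one group was C55C3.3 (log2 fold change 5.11, edgeR adjusted p = 0.0192), C55C3.6 and C55C3.7. Another was pmk-2 (2.25, 0.041), pmk-3 (1.98, 0.0369), both p38 MAP kinases, and islo-1 (2.18, 0.0486), which lie side by side; islo-1 shares 56 exonic bases with a noncoding gene on its own strand. The third was C27D8.2, C27D8.3 (2.61, 0.0267) and T23F6.1 (3.76, 0.0233). On chromosome I, tag-344 (5.24, 0.0192), fbxa-125 (5.68, 0.041; 5.05 without wild-type replicate 2) and B0511.11 (4.74, 0.00847) lay within 10 kb of each other. Single higher genes included dyf-3 (3.77, 0.0313; 4.36 without wild-type replicate 1), a gene of sensory cilia, and C08F11.7 (4.68, 0.00847) on chromosome IV.

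Outside the chromosome II run and beside plp-1, haf-6 and tiar-2, 2 more genes were lower. The gene sul-3 on the X chromosome, a sulfatase, held 50, 55 and 69 counts in wild-type and 0 in all mutant libraries, at least 61-fold lower (edgeR adjusted p = 0.0486). The piRNA locus 21ur-15625 on chromosome IV held 120 counts over wild-type and 3 over the mutant libraries, a ratio of 37.7 with a 95% counting interval from 13 to 186. Selection for poly(A) is not made to capture piRNAs, and which transcript these counts came from was not tested.

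Of the 24 genes of the run at 0 on chromosome II, 14 belong to the F-box and MATH/BTB families and 10 do not. Depth cannot account for the run, since 5799 counts were expected at the wild-type share and 1 was seen. A fall of the whole family to 0 is argued against by 362 family genes outside the run with at least 30 wild-type counts. Of these, 1 (fbxb-114, 32 and 0 counts) held 3 or fewer mutant counts. The tested family genes outside the run had a median log2 fold change of -0.18. The count of genes near 0 does not test a milder fall. Over all 370 tested members, with those of the run, 31 were lower and 5 higher at an unadjusted p under 0.05 (edgeR). A segment that the mutant strain lacks, or that differs too much from the reference for reads to align, may be the source: 22 run genes held at least 10 wild-type counts, and the longest other run of this kind in either group held 4 such genes. Without DNA reads this cannot be told apart from a block of genes silenced in the strain, whether by loss of plp-1 or by a linked or unlinked background change, and each stays open.

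The rise of the small RNA target genes could come from another mix of stages, germ cells or sperm in the mutant cultures. The 20 tested targets had a median log2 fold change of 1.13, below the highest median of 12 stage and cell lists (3.14, the major sperm proteins), while the 5 called ones lay between 4.01 and 9.21, above the largest value of a sperm gene (3.9). The median difference of mutant replicate 3 from the mean of the other mutant libraries was -0.34 for targets and -1.42 for sperm genes on the log2 scale; as the 5 were picked by their rise and this contrast rests on 1 library, the explanation stays open. Reads moved from the W09B7 pair to the F07B7 pair, or back, cannot by themselves raise both, and both pairs rose. Their summed counts then had to rise and add nothing to that. The sum of W09B7.2 and F07B7.2 rose by 5.50 on the log2 scale (edgeR adjusted p = 0.022), that of W09B7.1 and F07B7.1 by 9.14 (0.0344). Whether W09B7.2 and F07B7.2 rose separately or share the reads of a single copy stays open. Beside them, 3 other targets were called. A background difference between the strains and loss of silencing in the plp-1 mutant stay open too, and neither was tested, since the design holds 1 mutant strain.

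The share of higher genes on chromosome IV may come from background variants that stayed linked to plp-1 when the strain was made. The 702 tested genes within 2 Mb of plp-1 held 9 of the 18 genes, and without that window the odds ratio was 2.79 (95% interval 1.13 to 6.32). That interval takes genes as independent, and the genes left on chromosome IV include the neighbours C27D8.2, C27D8.3 and T23F6.1. The window and the neighbours were not taken out together. Whether the window, or a longer linked stretch, is the whole source therefore stays open. Counting neighbouring genes once, with the window kept, left 12 of 29 and an odds ratio of 3.49 (1.52 to 7.78). Sperm genes are frequent on chromosome IV (40 of 84 tested), and among genes without a sperm-like drop in mutant replicate 3 the odds ratio was 3.69 (1.71 to 7.77). Since that profile rests on 1 library, a part played by unlisted sperm genes cannot be told apart from an effect of the mutation.

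The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 52 genes and the highest other 17, and 1 of the 10 splits reached 52. For gene lists, 8 of the 10 splits gave at least the 10 lists of the real one, and the highest other gave 17. For transcripts, 2 of the 10 gave at least 12 and the highest other 23; for transcript use, 2 gave at least 12 and the highest other 13. The split that set wild-type replicate 1 with mutant replicates 1 and 2 gave 17 genes, 17 lists, 23 transcripts and 13 genes with changed use. Among the 4 splits that part all 3 pairs of replicate numbers, the other 3 gave 0 genes, with and without the block, up to 16 lists, up to 1 transcript and up to 10 genes with changed use.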
